A study of Mus musculus with 574 samples.

How the data were processed

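Single GMPs of C57Bl/6 mice treated with 5-FU were sorted 1 to a well, and cDNA was made with Smart-seq2 and Nextera XT, per the labels' protocols. Neither step marks the strand, so reads of a gene and of an antisense gene over it, such as Gm20655, cannot be told apart by strand. Reads counted as ambiguous have a row of their own, which is not in the gene totals. The protocol names both crushed and flushed bones and both 5-FU and control mice, and does not say which set came from which, nor whether the day 0 mice received the control injection. The deposited values are whole-number read counts per gene and cell, not normalized, which the authors made with GSNAP on the mm10 build and HTSeq 0.5.3p3, per the submitters' processing notes. Cells have no molecular identifiers, so PCR copies are counted, and intervals and zero limits cover counting error only.

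The labels list 574 cells in 6 sets, of which 573 had a matching column and 1 column was not used. Each table holds 46078 gene rows, 92 spike-in rows and 5 rows that name no gene. In the median cell these 5 rows took 91.1% of all reads, and reads not aligned took 79.2%. They were left out of totals and tests, as were the spike-ins. Gene IDs were matched by ID to GENCODE vM21 (GRCm38, the same build as mm10), with a symbol for 45143 of 46078. No 2 cells had identical counts (0 pairs).

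Cells with at least 50000 reads in genes and at least 1000 genes were kept. Cells are not replicates, so the counts of kept cells were summed within each set. The labels number 2 sets on day 8 and do not say that they came from separate mice, so p-values measure only the spread between these 2 sets, which may be technical. Genes were tested if they passed the edgeR count filter (filterByExpr, by day) and had a read in at least 10% of kept cells of a set, 15145 in all. The test used edgeR 4.0.16 (R 4.3.3), TMM factors, a mean per day, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05. The fit had 1 residual degree of freedom, a prior of 51.5 degrees of freedom and a common dispersion of 0.0755. Sets of other days were assumed to vary like the day 8 sets. Every day other than day 8 is 1 set, so day cannot be told apart from sex, bone preparation or plate where these differ.

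Gene lists were fixed for the sort markers, 13 cell types or stages, the cell cycle, stress and signalling pathways, metabolism and sex. Of these, 32 had at least 3 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation. The estimated correlation rests on the 1 residual degree of freedom of the fit, so that test could hardly pass for any list. A miss there decides nothing, while the preset correlation is an assumption that these data do not check. The RNA quality list of Malat1 and Neat1 has 2 members and was not tested as a list. Named genes were the 10 largest rises and 10 largest falls between days 8 and 0, and 5 of each in every other comparison. They came from called genes with a read in at least 20% of kept cells of a set, at least 32 CPM on either day and both day 8 sets on the same side. Also named were up to 4 members of each described list and 16 genes fixed in advance. Values of some list members are not reported here. Other genes, chosen after their values were seen, are Malat1, Neat1 and Slc34a2. A fold change against a day with 0 reads was bounded by setting that day to 3 reads at the TMM-scaled depth. These choices, the lists and the alternatives listed first below were made before the data were examined.

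Shares of cells with a read were taken after thinning each kept cell at random to 50000 reads, with exact 95% binomial intervals. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 without the cell cycle lists, and no doublet caller was run. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives were DESeq2 1.42.0 size factors or its Wald test, limma voom, no gene filter, no cell filter, cells with at least 200000 reads and 2000 genes, cells thinned to 50000 reads, each day 8 set left out, and the day 0 and 8 sets alone. Added after seeing the data were cells with at least 4000 genes, no day 14 set, no Slc34a2 and CT010467.1, and limma voom and DESeq2 on thinned cells.

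The tests were tried on simulated counts of the 15145 genes, with 50 genes at each of 4 fold sizes per comparison. The changed genes were drawn only from genes above a minimum of expected reads. The numbers called of 50 therefore do not cover genes with few reads. At log2 folds of −2, −1, 1 and 2, edgeR called 43, 9, 15 and 49 of 50 for day 8 against day 0, with 2 calls among unchanged genes. For day 10 against day 0 it called 39, 8, 5 and 46 with 13 false calls, for day 12 against day 0 it called 40, 2, 9 and 46 with 4, and for day 14 against day 0 it called 31, 6, 4 and 46 with 8. For day 10 against day 8 it called 42, 7, 3 and 48 with 1 false call, for day 12 against day 8 it called 43, 0, 13 and 44 with 3, and for day 14 against day 8 it called 38, 14, 22 and 50 with 9. Camera called a shifted list of 52 genes in each comparison and 0 other lists. Simulated genes were drawn independently of each other, and all sets were given the same spread. These counts therefore say nothing about lists with correlated members or about days that vary more than the day 8 sets.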

Results

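The series follows granulocyte/macrophage progenitors (GMPs) of mouse bone marrow after 5-fluorouracil (5-FU), given once at 150 mg/kg. This drug is a fluoropyrimidine that blocks thymidylate synthase and kills dividing cells. GMPs are the progenitors of neutrophils and monocytes. They were sorted as lineage-negative, c-Kit-positive, Sca-1-negative, CD34-positive and FcγR-positive single cells and sequenced with Smart-seq2, a full-length method without molecular identifiers. The labels give 6 sets of cells: 1 set each on days 0, 10, 12 and 14, and 2 replicate sets on day 8. Of 573 cells, 500 had at least 50000 reads in genes and at least 1000 genes with a read, and were kept. There were 92 on day 0, 90 and 93 in the first and second day 8 set, 93 on day 10, 85 on day 12 and 47 on day 14. Their median depth was 145093 reads in genes on day 0, 289939 and 214717 on day 8, 224022 on day 10, 158578 on day 12 and 79451 on day 14. Summed over kept cells, the sets held 16457271, 30691997, 25650670, 27333941, 17058337 and 4849678 reads. The question was how gene expression in GMPs changes over the weeks after 5-FU, so days 8, 10, 12 and 14 were compared with day 0, and days 10, 12 and 14 with day 8. Counts were summed over the cells of a set, so a change of level within cells is not separated from a change in the mix of cells. The largest changes named are those among genes with at least 32 CPM on either day and a read in at least 20% of kept cells of a set.

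The sets differed in ways other than day. Xist, the RNA that silences an X chromosome in females, had a read, in cells thinned to 50000 reads, in 84.8% of day 0 cells (78 of 92; exact 95% interval 75.8 to 91.4%) and 84.7% of day 12 cells, and in 4.30% of the second day 8 set and 2.13% on day 14. It had a read in 0 of 90 cells of the first day 8 set, which allows a share of up to 3.33%, and in 0 of 93 cells on day 10, which allows up to 3.23% at this thinned depth. Without thinning, Xist had a read in 92.4% and 95.3% of cells on days 0 and 12, 7.78% and 8.60% in the day 8 sets, 3.23% on day 10 and 2.13% on day 14. The Y-linked genes Eif2s3y or Kdm5d had a read in 8.70% and 7.06% of cells on days 0 and 12 and in 78.9%, 69.9%, 85.0% and 55.3% of cells of the first and second day 8 set, day 10 and day 14. Xist and one of these Y-linked genes were both read in 7 of 92 day 0 cells, 4 of 85 day 12 cells and 0 cells of the other sets. Without thinning the numbers were 14 on day 0, 14 on day 12, 5 and 6 in the day 8 sets, 3 on day 10 and 0 on day 14. The Y-linked genes Ddx3y and Uty, whose reads are uncertain beside their X-linked homologues, had a read without thinning in 92.4% and 60.9% of day 0 cells and in 63.5% and 54.1% of day 12 cells. Ddx3y stood at 17.4 and 5.42 CPM (read counts scaled to a common depth) on days 0 and 12 against 36.97 to 88.3 CPM in the other sets, and Uty at 6.19 and 3.90 CPM against 15.1 to 41.7 CPM. The sets of days 0 and 12 are called female below and those of days 8, 10 and 14 male, from Xist, Eif2s3y and Kdm5d alone. Slc34a2, a phosphate transporter, took a median of 18.03% of reads in kept cells on day 0, 9.68% and 16.3% on day 8, 13.4% on day 10, 16.9% on day 12 and 31.2% on day 14. The nuclear RNA Malat1 stood at 450 CPM on day 0, 172 and 259 on day 8, 199 on day 10, 309 on day 12 and 362 on day 14, and Neat1 at 98.2, 42.7 and 37.4, 36.2, 60.4 and 49.4 CPM. Both RNAs, which are retained in the nucleus and move with RNA quality, fell on day 8 (Malat1 log2 fold change −1.06, SE 0.27, adjusted p = 0.00894, and Neat1 −1.29, SE 0.26, adjusted p = 0.000983) and on day 10 (Malat1 −1.18, adjusted p = 0.0437, and Neat1 −1.44, adjusted p = 0.00778).

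On day 8, the summed RNA of GMPs held less of 10 of 14 monocyte genes and of 5 of 11 primary granule and granulocyte priming genes than on day 0. It held more of 7 of 17 stem and progenitor genes and of 4 of 5 erythroid genes, of which Gata1, Klf1 and Hbb-bt had reads in few cells. Elane, which encodes neutrophil elastase (ENSMUSG00000020125, mm10 chromosome 10, 79886247 to 79888215), fell from 17289 CPM to 2594 and 2894 CPM in the 2 sets (log2 fold change −2.66, SE 0.31, adjusted p = 1.33e-08). Ly6c2, a surface antigen of monocytes (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), fell from 4942 CPM to 735 and 241 CPM (−3.34, SE 0.34, adjusted p = 5.72e-10). Ifitm1, an interferon-induced membrane protein gene active in primitive progenitors (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), rose from 39.1 CPM to 437 and 798 CPM (3.98, SE 0.36, adjusted p = 8.15e-12). In the same sets Malat1 and Neat1 fell as given above. Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose by 2.71 (SE 0.32), and Emilin2, an extracellular matrix gene, by 2.56 (SE 0.31). Of 15145 genes tested, 396 rose and 457 fell between 1 day 0 set and 2 day 8 sets, and 40 of these calls lay on chromosome X and 5 on Y.

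**Figure D1:**
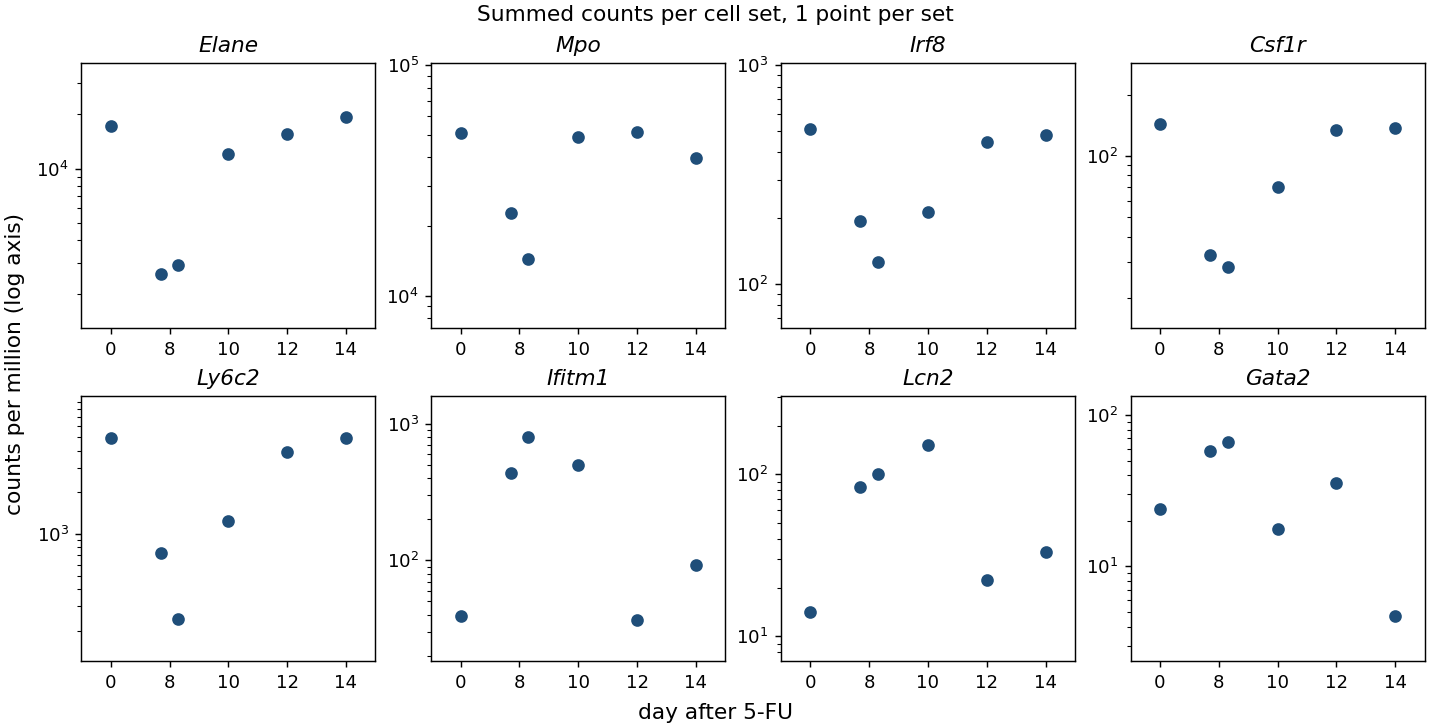
CPM (vertical log axis) of 8 genes in each of the 6 cell sets by day after 5-FU (horizontal axis), 1 point per set and 2 sets on day 8. Elane stood at 2594 and 2894 on day 8 against 17289 on day 0 and 19321 on day 14, and Ifitm1 at 437 and 798 on day 8 against 39.1 on day 0.

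The other genes with the largest rises on day 8 were Eif2s3y (6.40, SE 0.46), and Ctla2a, a cysteine protease inhibitor gene (5.65, SE 0.55, from 0.84 to 37.2 and 47.8 CPM). They were followed by the processed pseudogene Gm7676 (3.28), the prostaglandin E receptor gene Ptger3 (3.10, SE 0.43), Ms4a2, the beta chain of the high-affinity IgE receptor of mast cells and basophils (3.03, SE 0.45), and the carbonic anhydrase gene Car2 (2.52, SE 0.32). The microRNA locus Mir6236 was also called (2.60, SE 0.53), but its day 8 sets stood at 347 and 3274 CPM against 300 CPM on day 0. Its value was 0.21 without the second set. Besides Elane and Ly6c2, the largest falls were those of Xist (−7.63, SE 0.40), Ifi209 (−3.34, from 98.4 to 17.6 and 1.70 CPM in the day 8 sets), H2-Q6, a nonclassical major histocompatibility class I gene (−3.18), Ly86, a partner of a Toll-like receptor homologue (−3.12, SE 0.34), and the cathepsin gene Ctsh (−2.92). The others were Ly6c1 (−3.36), Gm5960 (−3.35) and I830127L07Rik (−2.97). The last 3 lie with Ly6c2 on chromosome 15, between 75044018 and 75135128, and 2 of them are annotated as pseudogenes. Reads of near-identical copies are uncertain there and between H2-Q6 and H2-Q7. Without the first day 8 set the value was −5.84 for Ifi209 and −4.71 for Ctsh.

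Of the 14 tested monocyte genes, 10 fell and 4 did not pass, with a median log2 fold change of −1.61 (11 fell when adjusted over the list alone). Csf1r, the receptor of macrophage colony-stimulating factor (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), fell by 2.24 (SE 0.26, adjusted p = 1.07e-08), and Irf8, the transcription factor that directs monocyte fate (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694), fell by 1.67 (SE 0.27, adjusted p = 2.34e-05). The camera adjusted p of the list was 1.67e-20, and adjusted p = 0.597 with an estimated correlation. Here and below, the test with an estimated correlation rests on 1 residual degree of freedom and could hardly pass for any list. Of 11 genes of primary granules and granulocyte priming, 5 fell and 6 did not pass, 5 also when adjusted over the list alone, with a median of −0.46. They were Elane, the myeloperoxidase gene Mpo (−1.44, SE 0.33, adjusted p = 0.00417), the ficolin gene Fcnb (−2.52), Gstm1 (−1.20) and the granulocyte transcription factor gene Cebpe (−1.19, adjusted p = 0.0287). Camera gave this list adjusted p = 0.000393, and adjusted p = 0.597 with an estimated correlation. Gfi1 (0.48, adjusted p = 0.419) and Cebpa (0.41, adjusted p = 0.453), which encode transcription factors of granulocyte fate, were not called. Fcgr3, which encodes a receptor in the FcγR sort gate, fell by 1.41 (SE 0.25, adjusted p = 0.000174), while the other sort genes Kit (−0.69), Cd34 (0.66) and Ly6a (−0.64), which encode c-Kit, CD34 and Sca-1, did not pass.

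Of 4 eosinophil genes, the granule protein genes Prg3 (−3.93, SE 0.52) and Prg2 (−2.44, SE 0.76) fell and Epx and Siglecf did not pass, the same numbers as when adjusted over the list alone. Prg2 stood at 420 CPM on day 0 and at 0 and 155 CPM in the day 8 sets. The list's median was −4.12 without the second day 8 set and −0.65 without the first, against −1.29 with both (camera adjusted p = 0.000218, and adjusted p = 0.597 with an estimated correlation). Of 7 late neutrophil genes, Lcn2 and S100a9 (3.47) rose and Ly6g (−3.26, from 1.14 to 0.11 CPM) fell, against 3 and 1 adjusted over the list alone, with a median of 0.88, which was 0.046 without the second day 8 set (camera adjusted p = 0.048, and adjusted p = 0.597 with an estimated correlation). S100a9 stood at 2.88 CPM on day 0 and at 4.31 and 59.9 CPM on day 8. Without the second day 8 set its value was 0.58 and that of Prg3 −6.12, and without the first that of Prg2 was −1.43. None of the 5 macrophage genes passed over all genes and 4 were lower when adjusted over the list alone, with a median of −1.24, examples being the iron exporter gene Slc40a1 (−1.70) and the adhesion gene Vcam1 (−1.24). That list had camera adjusted p = 0.00166, and adjusted p = 0.597 with an estimated correlation.

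Of 17 tested genes of stem cells and multipotent progenitors, 7 rose and 10 did not pass, 7 also when adjusted over the list alone, with a median of 1.14. Examples are Ifitm1, the homeobox gene Hoxa9 (1.67, SE 0.37, adjusted p = 0.00288), the RNA-binding protein gene Msi2 (1.68) and the cytokine receptor gene Flt3 (1.43, SE 0.42, adjusted p = 0.0318). Camera gave adjusted p = 2.14e-05, and adjusted p = 0.597 with an estimated correlation. Of 5 erythroid genes 4 rose and 1 did not pass, 4 also when adjusted over the list alone, with a median of 2.96: Car2, the erythroid transcription factor gene Gata1 (2.96, SE 0.63, from 2.34 to 15.3 and 21.2 CPM), and Klf1 and Hbb-bt, which had 0 reads on day 0. At 3 reads over the day 0 set, Klf1 was higher by at least 5.97 and Hbb-bt by at least 3.74 on the log2 scale, and the list's median with these bounds was 2.96. Hbb-bt stood at 4.09 and 0.397 CPM in the day 8 sets, with 134 and 11 reads. Without the first set it was higher by at least 1.14. On day 8, without thinning, Klf1 had a read in 11.1% and 19.4% of cells of the 2 sets and Gata1 in 9 of 90 cells and in 21.5%. Hbb-bt had one in 11.1% and 4.30%, and Car2 in 68.9% and 75.3%. The camera adjusted p was 7.83e-09, and adjusted p = 0.597 with an estimated correlation.

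Several growth and metabolism lists passed camera towards higher values on day 8. Of 25 ribosome biogenesis genes 5 rose, among them Bop1 (1.23, SE 0.28), Nolc1 (1.09), Nop14 (1.07) and Ddx21 (0.90), and 17 when adjusted over the list alone. The list's median was 0.73 (camera adjusted p = 2.71e-09, and adjusted p = 0.597 with an estimated correlation). Of 17 glycolysis genes 5 rose, 8 adjusted over the list alone, with a median of 0.67, including the glucose transporter genes Slc2a3 (2.99, SE 0.59) and Slc2a1 (1.73, SE 0.40) and the lactate dehydrogenase gene Ldha (1.20). Camera gave adjusted p = 2.41e-06, and adjusted p = 0.597 with an estimated correlation. Of 19 cholesterol synthesis genes 2 rose, among them Cyp51 (1.42), 3 adjusted over the list alone, with a median of 0.70 (camera adjusted p = 0.00139, and adjusted p = 0.744 with an estimated correlation). Without the first day 8 set that median was 0.40 and Cyp51 stood at 0.85. Of 19 genes of fluoropyrimidine and thymidylate metabolism 3 rose, 5 adjusted over the list alone, namely Shmt2 (0.99) and Mthfd2 (0.99) of the mitochondrial folate pathway and the ribonucleotide reductase gene Rrm2 (1.0). Tyms, which encodes thymidylate synthase, the target of 5-FU, stood at 131 CPM on day 0 and 127 CPM on day 8 (−0.05, SE 0.26, adjusted p = 0.946). The median of this list was 0.38 (camera adjusted p = 0.00812, and adjusted p = 0.597 with an estimated correlation). Of 42 DNA replication genes Ccne2 (1.22, and 0.73 without the first day 8 set), Rrm2 and Chaf1b (0.93) rose and 39 did not pass, 3 also adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.00414, and adjusted p = 0.787 with an estimated correlation). No oxidative phosphorylation gene of 22 passed in edgeR over all genes or over the list alone, their median was 0.21, and Cyc1 stood at 0.64 (camera adjusted p = 0.0453, and adjusted p = 0.597 with an estimated correlation).

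The immediate early, cytokine receptor, interferon response and cell cycle inhibitor lists passed camera towards lower values on day 8. CPM are shares of the reads of a set. The median ratio of reads in genes to spike-in reads was 40.9 on day 0 and 78.9 and 71.8 in the day 8 sets. A lower share on day 8, in these lists and in Malat1 and Neat1, therefore need not mean less RNA per cell. Of 16 immediate early and dissociation stress genes 5 fell and 11 did not pass, with 9 lower and 1 higher when adjusted over the list alone and a median of −0.76. They included Fos (−1.21, SE 0.26) and Jun (−1.17, SE 0.26), which encode the AP-1 transcription factor. The heat shock genes Hspa1a (−1.81) and Hspa1b (−3.04), near-identical copies whose split of reads is uncertain, fell too. Camera gave adjusted p = 2.14e-05, and adjusted p = 0.597 with an estimated correlation. Of 15 cytokine receptor genes 2 rose and 4 fell, 2 and 7 adjusted over the list alone, with Il6ra (−1.54, SE 0.29) and Csf2ra (−1.01) lower beside Csf1r, and a median of −0.60 (camera adjusted p = 0.00936, and adjusted p = 0.597 with an estimated correlation). Of 23 interferon response genes 3 fell, among them Usp18 (−2.34) and Ifi27l2a (−2.78), and Oasl1 (2.55) rose, 4 lower and 1 higher adjusted over the list alone, with a median of −0.63 (camera adjusted p = 0.00388, and adjusted p = 0.597 with an estimated correlation). Of 10 cell cycle inhibitors the antiproliferative genes Btg2 (−1.06) and Btg1 (−1.23) fell, with 4 lower and 1 higher adjusted over the list alone and a median of −0.70 (camera adjusted p = 0.0318, and adjusted p = 0.597 with an estimated correlation). The sex-linked genes, with 3 of 5 higher and 1 lower (4 and 1 adjusted over the list alone), had a median of 1.32 (camera adjusted p = 0.0318, and adjusted p = 0.597 with an estimated correlation).

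Camera did not pass 14 of the 32 lists on day 8. They were sort markers (adjusted p = 0.497), dendritic cell (0.521), megakaryocyte (0.0578, with 3 of 5 genes higher), basophil and mast cell (0.121, with 4 of 8 higher and 1 lower) and early lymphoid and B cell (0.168). They also were T and NK cell (0.312), stroma and endothelium (0.314), mitosis (0.323) and p53 targets (0.314, with 3 of 21 higher and 1 lower). The rest were Wnt and beta-catenin (0.893), TGF-beta response (0.814), NF-kappaB and inflammation (0.846), BCL2 family and caspases (0.104) and adhesion and marrow retention (0.943). The proliferation gene Mki67 (−0.43, adjusted p = 0.391), the beta-catenin gene Ctnnb1 (0.36, adjusted p = 0.507), Myc (0.66, adjusted p = 0.17) and the p53 target and cell cycle inhibitor gene Cdkn1a (0.96, adjusted p = 0.136) were not called. With every cell thinned to 50000 reads edgeR called 0 genes (1431 at an unadjusted p under 0.05), limma voom 0 (1392) and DESeq2 49. On unthinned sums DESeq2 called 363, 832 of the 832 calls tested on thinned sums kept their direction, and days 8 and 0 also differ in sex and in depth. Thinned sums are drawn from the same reads, so here and below a shared direction is hardly a check on the calls.

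**Figure D2:**
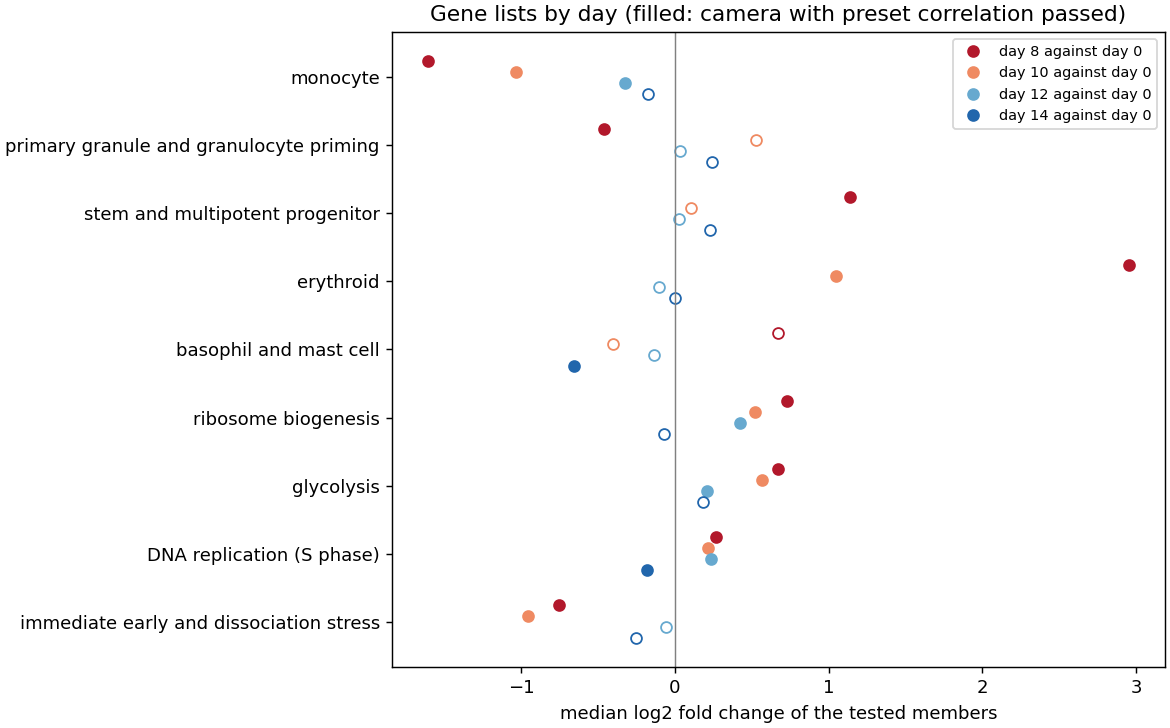
Median log2 fold change against day 0 (horizontal axis) of the tested members of 9 gene lists (vertical axis) on days 8, 10, 12 and 14, with filled points where camera with a preset correlation gave an adjusted p under 0.05. The monocyte list stood at −1.61 on day 8, −1.03 on day 10, −0.32 on day 12 and −0.17 on day 14.

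Cell by cell, Irf8 RNA was found in a smaller share of GMPs on day 8. In cells thinned to 50000 reads, Irf8 had a read in 84.8% of day 0 cells (exact 95% interval 75.8 to 91.4%). It had a read in 54 of 90 cells (49.1 to 70.2%) and 46 of 93 cells (38.9 to 60.03%) of the day 8 sets. On day 10 the share was 68.8%, on day 12 it was 68 of 85 cells and on day 14 it was 78.7%. Csf1r had a read in 71.7% of day 0 cells, 33.3% and 30.1% on day 8, 51.6% on day 10, 70.6% on day 12 and 55.3% on day 14. Gfi1 had a read in 45.7% of cells on day 0, 41.1% and 43.01% on day 8 and 59.1% on day 10 (48.5 to 69.2%). Both Irf8 and Gfi1 had a read in 33.7% of day 0 cells (24.2 to 44.3%), 21.1% and 21.5% of day 8 cells and 35.5% of day 10 cells. Without thinning the shares were 47.8%, 53.3%, 53.8% and 68.8%, so their order depends on depth. Gata2, a transcription factor gene of stem, mast and basophil cells, had a read in 17.4% of day 0 cells, 35.6% and 52.7% of day 8 cells, 21.5% on day 10, 23.5% on day 12 and 8.51% on day 14. Without thinning the Irf8 share was 94.6% on day 0 and 81.1% and 83.9% on day 8.

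**Figure D3:**
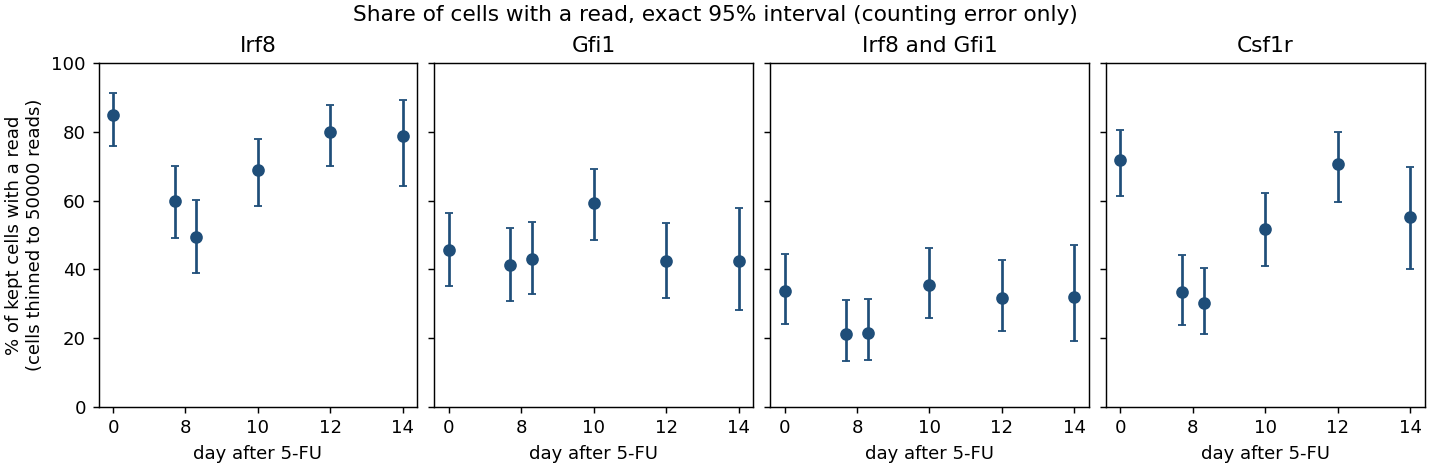
Share of kept cells, each thinned to 50000 reads, with a read of Irf8, Gfi1, both or Csf1r (vertical axis, %) in each cell set by day after 5-FU (horizontal axis), with the exact 95% interval from counting error as bars. Irf8 stood at 84.8% on day 0 and at 49.5% in the second day 8 set.

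On day 10, Elane and Mpo were not called against day 0, while 4 of 14 monocyte genes fell. Elane stood at 12127 CPM against 17289 on day 0 (−0.51, SE 0.37, adjusted p = 0.604) and Mpo at 48985 against 50756 (−0.05, SE 0.40, adjusted p = 0.972). Irf8 (−1.26, SE 0.33, adjusted p = 0.0292), Ly86 (−2.77, SE 0.43) and Ly6c2 (−2.0, SE 0.42) fell. Ifitm1 rose by 3.68 (SE 0.37), Lcn2 by 3.43 (SE 0.35) and Cxcl10, an interferon-induced chemokine gene, by 2.67 (SE 0.40, from 23.9 to 152 CPM). Between 1 set on each day, 104 genes rose and 116 fell, 14 of them on chromosomes X and Y (9 and 5).

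The largest changes on day 10 also took in Eif2s3y (6.72), Gm7676 (3.25), Xist (−10.63), H2-Q6 (−3.82), H2-Q7 (−3.12), Prg2 (−3.99, SE 1.03) and AA474408 (−4.68, from 111 to 4.35 CPM), a locus whose coding status is unsettled. The monocyte list had 4 of 14 lower, with Cx3cr1 (−2.08) beside the genes above, and 9 adjusted over the list alone, with a median of −1.03 (camera adjusted p = 1.29e-08, and adjusted p = 0.868 with an estimated correlation). Camera passed 11 of 32 lists here, each with adjusted p = 0.868 with an estimated correlation. Higher were the late neutrophil (2 of 7 rose, Lcn2 and S100a9, 3 adjusted over the list alone, median 1.34), erythroid (1 of 5 rose, 3 adjusted over the list alone, median 1.05, with Klf1 higher by at least 4.80) and ribosome biogenesis (0 of 25 passed in edgeR, 1 adjusted over the list alone, median 0.52) lists. Also higher were glycolysis (Slc2a1 rose, of 17, 6 adjusted over the list alone, median 0.57), cholesterol synthesis (1 of 19 rose, 1 adjusted over the list alone, median 0.25), DNA replication (0 of 42 passed in edgeR over all genes or the list alone, median 0.22) and the sex-linked genes (4 higher and 1 lower of 5). Malat1 and Neat1 fell in the same comparison. Lower beside the monocyte list were immediate early and dissociation stress (Ier2, −1.37, and Egr1, −3.16, fell of 16, 8 adjusted over the list alone, median −0.96), cell cycle inhibitors (Btg2 fell by 1.41, of 10, 3 adjusted over the list alone, median −0.79) and eosinophil (2 of 4 fell, 2 lower and 1 higher adjusted over the list alone, median −2.30). Gfi1 (0.93, adjusted p = 0.209), Cebpa (0.53), Cebpe (−0.30), Kit (−0.25), Cd34 (0.07), Fcgr3 (0.30), Ly6a (−1.03), Flt3 (0.05), Mki67 (−0.38), Ctnnb1 (0.23), Myc (0.23), Cdkn1a (−0.87) and Tyms (0.17) were not called.

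The edgeR calls between days 10 and 0 compare a male with a female set. DESeq2 called 52 genes, and on thinned cells edgeR called 0 (706 at an unadjusted p under 0.05), limma voom 0 (575) and DESeq2 4, with 217 of 217 tested calls in the same direction on thinned sums.

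Day 12 gave the fewest called genes of the comparisons with day 0. Itgb7, which encodes an integrin beta chain, rose by 1.77 (SE 0.41, adjusted p = 0.0444). Prg2 had 0 reads on day 12 against 420 CPM on day 0, so it was lower by at least 11.23 on the log2 scale at 3 reads over the day 12 set. Its reads on day 0 came from 29.3% of cells, without thinning. The 2 day 8 sets stood at 0 and 155 CPM, so sets of the same day can differ by as much. The next largest falls were those of the glycogen synthase gene Gys2 (−2.31, SE 0.41), Tbata (−2.03, SE 0.40), the adaptor gene Sh2b3, a brake on cytokine signalling (−1.77, SE 0.32, adjusted p = 0.00151), and the ribosomal protein gene Rps28 (−1.72). Over days 0, 8 (2 sets), 10, 12 and 14, Tbata stood at 246, 33.6, 110, 55.7, 59.98 and 1048 CPM. Gys2 stood at 56.6, 7.76, 21.3, 10.6, 11.4 and 146 CPM, and Rps28 at 44.6, 9.01, 26.6, 12.3, 13.5 and 204 CPM. Each stood below its day 0 value on days 8, 10 and 12 and above it on day 14. The median Slc34a2 share did the same, at 18.03%, 9.68%, 16.3%, 13.4%, 16.9% and 31.2% over these sets, though on day 12 it lay close to day 0. Whether these 3 falls follow the amount of cDNA per cell and not a change in the genes was not tested. In total 10 genes rose and 16 fell, both sets were female, and 1 call lay on Y. Irf8 stood at 447 CPM against 512 (−0.20, SE 0.32, adjusted p = 0.963), Elane at 15598 against 17289 (−0.15) and Mpo at 51139 against 50756 (0.01).

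Among genes not called on day 12 that met the same limits of CPM and cells, those with the largest higher values were AA474408 (3.0, adjusted p = 0.0706), Mir6236 (2.16), S100a8 (1.57) and Opa3 (1.58). Gfi1 (0.80), Cebpa (0.17), Cebpe (−0.15), Kit (0.15), Cd34 (0.48), Fcgr3 (−0.10), Ly6a (−1.55), Flt3 (−0.18), Mki67 (−0.44), Ctnnb1 (−0.11), Myc (0.27), Cdkn1a (0.54) and Tyms (0.13) were not called either. Camera passed 7 of 32 lists, each with adjusted p = 0.989 with an estimated correlation. The eosinophil list had Prg2 and Prg3 (−5.42) lower of 4, 2 adjusted over the list alone (median −3.14, camera adjusted p = 3.01e-09). Late neutrophil (median 1.23, 1 of 7 higher adjusted over the list alone), ribosome biogenesis (0.43, none adjusted over the list alone), glycolysis (0.21, 4 of 17 higher adjusted over the list alone) and DNA replication (0.24, 1 of 42 lower adjusted over the list alone) passed towards higher values. The monocyte list (−0.32, 2 of 14 lower adjusted over the list alone) passed towards lower ones. None of these 5 lists had a member called over all genes by edgeR. Of 23 interferon response genes Rtp4 fell (−4.71, from 6.25 to 0.23 CPM), 1 also adjusted over the list alone, and the list's median was −0.33 (camera adjusted p = 0.046). The count of 26 became 66 without the day 14 set in the fit, 63 with cells of at least 200000 reads, 73 without a gene filter, 81 with cells of at least 4000 genes, 16 with DESeq2 size factors, 11 in limma voom and 4 in DESeq2. On thinned cells edgeR (517 at an unadjusted p under 0.05), limma voom (356) and DESeq2 (71) each called 0, and 26 of 26 calls kept their direction.

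On day 14, Irf8, Elane and Mpo were not called against day 0, and several loci outside the fixed lists rose. Irf8 stood at 481 CPM (−0.09, SE 0.32, adjusted p = 0.944), Elane at 19321 CPM (0.16, SE 0.37, adjusted p = 0.906) and Mpo at 39628 CPM (−0.36, SE 0.40, adjusted p = 0.771). Lrrc4b, which encodes a synaptic adhesion protein, rose by 4.09 (SE 0.71, from 3.73 to 63.6 CPM). AA474408 (4.90, SE 0.80), Mir6236 (3.87, SE 0.59) and the cyclin-dependent kinase gene Cdk14 (3.66, SE 0.54) rose as well. Apoe, which encodes apolipoprotein E (−2.40, SE 0.38), Pja2 (−2.28) and the p53 target Sesn1 (−2.25, SE 0.43) fell. In the same cells Slc34a2 took a median of 31.2% of reads against 18.03% on day 0, and the median number of genes with a read was 5258 against 6740. In total 130 genes rose and 109 fell, 15 of them on X and 5 on Y, with Eif2s3y (6.45) and Xist (−9.46) among them.

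Prg2 had 0 reads on day 14, as in the first day 8 set but not the second, and was lower by at least 9.13, and Prg3 fell by 4.58 (SE 0.79). These were 2 of the 4 eosinophil genes, 2 also adjusted over the list alone, with a list median of −3.21 (camera adjusted p = 3.52e-05, and adjusted p = 0.898 with an estimated correlation). Of 8 basophil and mast cell genes Gata2 (−2.33, SE 0.45) and Prss34 (0 reads on day 14, at least 4.56 lower) fell, 3 adjusted over the list alone, with a median of −0.66 (camera adjusted p = 5.54e-05, and adjusted p = 0.898 with an estimated correlation). Of 23 interferon response genes Xaf1 (−5.62), Rtp4 (at least 3.06 lower) and Ifi27l2a (at least 2.92 lower) fell, 4 adjusted over the list alone, with a median of −0.62 (camera adjusted p = 0.000291, and adjusted p = 0.898 with an estimated correlation). Of 42 DNA replication genes Casp8ap2 (−2.19) and Brip1 (−1.62) fell, 4 adjusted over the list alone, with a median of −0.18 (camera adjusted p = 0.0311, and adjusted p = 0.898 with an estimated correlation). The sex-linked list also passed (4 of 5 higher and 1 lower, camera adjusted p = 1.41e-06, and adjusted p = 0.898 with an estimated correlation), making 5 of 32 lists. Gfi1 (0.51), Cebpa (−0.02), Cebpe (−0.60), Kit (0.14), Cd34 (0.05), Fcgr3 (0.22), Ly6a (0.21), Flt3 (0.69), Mki67 (−0.45), Ctnnb1 (−0.08), Myc (0.15), Cdkn1a (−0.55) and Tyms (−0.21) were not called.

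The day 14 against day 0 count moved to 564 genes without a cell filter (380 higher and 184 lower), to 1717 with cells of at least 200000 reads (564 and 1153, from 4 cells on day 14), to 96 in limma voom (77 and 19) and to 67 in DESeq2 (47 and 20). On thinned cells edgeR called 0 genes (1227 at an unadjusted p under 0.05), limma voom 0 (709) and DESeq2 12, with 235 of 235 tested calls in the same direction on thinned sums.

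Between days 8 and 10, all in male sets, 3 of 11 primary granule and granulocyte priming genes rose, and 3 of 8 basophil and mast cell genes and 2 of 17 stem and progenitor genes fell. Elane rose by 2.14 (SE 0.31, adjusted p = 1.06e-05), Mpo by 1.39 (SE 0.33, adjusted p = 0.0252) and Fcgr3 by 1.70 (SE 0.25, adjusted p = 2.26e-05). Cxcl10 rose by 4.14 (SE 0.33, from 11.9 and 5.27 CPM on day 8), the cortisone reductase gene Hsd11b1 by 1.92, the leukotriene receptor gene Ltb4r1 by 1.85 and the pseudogene Gstm2-ps1 by 1.90, whose reads are uncertain beside related glutathione transferase genes. Ms4a2 (−3.40, SE 0.45), the vascular growth factor gene Angpt1 (−2.32, SE 0.39), Ctla2a (−1.83, SE 0.41) and Cdkn1a (−1.83, SE 0.40, adjusted p = 0.00843) fell. AA474408 (−7.43) and Mir6236 (−4.84) were called too, with the day 8 sets at 41.2 and 1458 CPM and at 347 and 3274 CPM against 4.35 and 63.4 CPM on day 10. Without the second set the values were −3.24 and −2.45. In total 73 genes rose and 47 fell, 7 of them on X and none on Y.

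Camera passed 14 of 32 lists between days 10 and 8. None of these passed with an estimated correlation. Of 11 primary granule and granulocyte priming genes 3 rose, Elane, Mpo and Gstm1 (1.75), and 8 adjusted over the list alone (median 0.90, camera adjusted p = 1.4e-16, and adjusted p = 0.759 with an estimated correlation). Of 8 basophil and mast cell genes Ms4a2, Gata2 (−1.82) and Cpa3 (−1.48, −0.75 without the first day 8 set, and 0.00060 on thinned cells in edgeR) fell, with 5 lower and 1 higher adjusted over the list alone (median −1.14, and −0.70 without the first day 8 set, camera adjusted p = 3.14e-07, and adjusted p = 0.759 with an estimated correlation). Monocyte genes had 3 of 14 higher, Csf1r (1.20), Ly6c2 (1.34, and 2.34 and 0.75 without the first and the second day 8 set) and Cybb (1.05), and 4 adjusted over the list alone (median 0.35, and 1.02 and 0.23 without the first and the second day 8 set, camera adjusted p = 4.69e-06, and adjusted p = 0.759 with an estimated correlation). Of 23 interferon response genes Usp18 rose (2.79, SE 0.59), 1 also adjusted over the list alone (median 0.61, camera adjusted p = 2.01e-07, and adjusted p = 0.759 with an estimated correlation). Without thinning, Usp18 had a read in 10.0% and 12.9% of cells of the day 8 sets and in 14.0% on day 10. Cytokine receptors had 3 of 15 higher, among them Il6ra (1.22) and Ifngr1 (1.02), with 4 higher and 1 lower adjusted over the list alone (median 0.44, and adjusted p = 0.759 with an estimated correlation). Of 17 stem and multipotent progenitor genes Angpt1 and Adgrg1 (−1.06) fell, 4 adjusted over the list alone (median −0.46, and −0.71 without the first day 8 set, and adjusted p = 0.759 with an estimated correlation). Of 5 erythroid genes Car2 fell (−1.63), 2 adjusted over the list alone (median −1.63). That list and the macrophage list (0 of 5 over all genes in edgeR, 2 higher adjusted over the list alone, median 0.85) had adjusted p = 0.759 with an estimated correlation. The sort marker list (Fcgr3 rose, of 7, 1 adjusted over the list alone, median 0.44, and 0.17 without the first day 8 set) and the late neutrophil list (0 of 7 in edgeR over all genes or the list alone, median 0.46, and 0.85 without the second day 8 set) had adjusted p = 0.813 with an estimated correlation. The dendritic cell (0 of 3, 1 lower adjusted over the list alone, median −0.92, and −0.50 without the second day 8 set), megakaryocyte (0 of 5, 2 lower adjusted over the list alone, median −1.14, and −0.74 without the second day 8 set) and fluoropyrimidine (Smug1 fell, of 19, 2 adjusted over the list alone, median −0.20, and −0.078 without the first day 8 set) lists had adjusted p = 0.813 with an estimated correlation. Ribosome biogenesis (0 of 25 in edgeR over all genes or the list alone, median −0.17, and −0.076 and −0.32 without the first and the second day 8 set) had adjusted p = 0.841 with an estimated correlation. Irf8 (0.41), Gfi1 (0.45), Cebpa (0.12), Cebpe (0.89), Kit (0.44), Cd34 (−0.60), Ly6a (−0.39), Flt3 (−1.38), Mki67 (0.05), Ctnnb1 (−0.13), Myc (−0.43) and Tyms (0.22) were not called.

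The count of 120 genes became 75 with DESeq2 size factors, 43 with cells of at least 200000 reads, 186 with cells of at least 4000 genes and 45 in DESeq2. With thinned cells edgeR called 0 (581 at an unadjusted p under 0.05), limma voom 0 (574) and DESeq2 7, and 115 of 116 tested calls kept their direction on thinned sums.

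Between days 8 and 12, 7 of 14 monocyte genes and 3 of 11 primary granule and granulocyte priming genes rose, and 3 of 17 stem and progenitor genes and 4 of 5 erythroid genes fell. Ly6c2 rose by 3.02 (SE 0.34, adjusted p = 8.94e-09), Elane by 2.51 (SE 0.31), Irf8 by 1.48 (SE 0.27, adjusted p = 0.00026), Mpo by 1.45 (SE 0.33) and Fcgr3 by 1.31 (SE 0.26). Ifi209 (2.98) and Ctsh (2.76) rose as well. Their values were 5.48 and 4.56 without the first day 8 set. Ifitm1 (−4.08, SE 0.36), Car2 (−3.16, SE 0.33) and Flt3 (−1.60, SE 0.43, adjusted p = 0.0231) fell. Day 12 was female and day 8 male, and Xist (7.42), Eif2s3y (−5.90), Ddx3y (−3.01), H2-Q6 (3.21) and Gm7676 (−4.01) were the other genes with the largest changes. Of the 211 higher and 167 lower genes, 16 lay on X and 4 on Y.

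Camera passed 16 of 32 lists between days 12 and 8, each with adjusted p = 0.753 with an estimated correlation. Monocyte genes had 7 of 14 higher, with Csf1r (2.13), Ly86 (2.74) and the coagulation factor gene F13a1 (1.59) among them, and 9 higher and 1 lower adjusted over the list alone (median 1.39). Of 11 primary granule and granulocyte priming genes Elane, Mpo and Fcnb (2.95) rose, 4 adjusted over the list alone (median 0.46). Erythroid genes had 4 of 5 lower, among them Klf1 (−5.60) and Gata1 (−3.43), 4 also adjusted over the list alone (median −3.43). Of 17 stem and multipotent progenitor genes Ifitm1, Adgrg1 (−1.16) and Flt3 fell, 5 adjusted over the list alone (median −0.93). Immediate early genes had 3 of 16 higher, Hspa1a (2.21), Jun (1.45) and Fos (1.19), with 7 higher and 1 lower adjusted over the list alone (median 0.86). Of 21 p53 targets Perp (−6.73, SE 0.74, from 23.3 and 27.4 to 0.23 CPM) and Pmaip1 (−2.10), which promote cell death, fell, with 2 lower and 1 higher adjusted over the list alone (median −0.23). Cytokine receptors had 3 of 15 higher and 1 lower, 7 and 1 adjusted over the list alone (median 0.64). Basophil and mast cell genes had 2 of 8 lower, Mcpt8 (−1.38, and −0.88 without the first day 8 set) and Ms4a2 (−1.54), with 5 lower and 2 higher adjusted over the list alone (median −0.82). Eosinophil genes had 1 of 4 lower, Prg2 (0 reads on day 12, at least 8.67 lower, and 0 and 155 CPM in the day 8 sets), 2 adjusted over the list alone (median −1.11, −1.95 without the first day 8 set, and 0.36 without the second day 8 set, the only one of that day with Prg2 reads). Macrophage genes had 1 of 5 higher, Vcam1 (2.23), 1 also adjusted over the list alone (median 1.27, and 0.64 without the second day 8 set). Mitosis (median −0.19), ribosome biogenesis (−0.28), glycolysis (−0.37), oxidative phosphorylation (−0.23) and cholesterol synthesis (−0.51) passed towards lower values with no member called by edgeR over all genes or over the list alone. Without the first day 8 set these medians were −0.12 for mitosis, −0.17 for ribosome biogenesis, −0.24 for glycolysis and −0.083 for cholesterol synthesis, and without the second −0.43 for ribosome biogenesis. The sex-linked list (1 of 5 higher and 4 lower, the same adjusted over the list alone) was the last.

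Gfi1 (0.32), Cebpa (−0.24), Cebpe (1.03), Kit (0.84, adjusted p = 0.0742), Cd34 (−0.18), Ly6a (−0.91), Mki67 (−0.02), Ctnnb1 (−0.47), Myc (−0.39), Cdkn1a (−0.42) and Tyms (0.18) were not called between days 12 and 8. DESeq2 called 171 genes, and on thinned cells edgeR called 0 (1134 at an unadjusted p under 0.05), limma voom 0 (1041) and DESeq2 44, with 376 of 376 tested calls in the same direction on thinned sums.

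Between days 8 and 14, both in male sets, 9 of 14 monocyte genes and 5 of 11 primary granule and granulocyte priming genes rose. Of the basophil and mast cell genes 4 of 8 fell, of the erythroid genes 3 of 5, of the DNA replication genes 10 of 42 and of the ribosome biogenesis genes 13 of 25. Elane rose by 2.82 (SE 0.31, adjusted p = 7.5e-10), Ly6c2 by 3.35 (SE 0.34), Irf8 by 1.58 (SE 0.27, adjusted p = 2.43e-05), Fcgr3 by 1.62 (SE 0.26), Mpo by 1.08 (SE 0.34, adjusted p = 0.0226) and Kit by 0.83 (SE 0.27, adjusted p = 0.0277). Ctla2a (−5.82, SE 0.67), Ms4a2 (−5.23, SE 0.62), Angpt1 (−4.23, SE 0.53), Car2 (−4.01, SE 0.38), Gata2 (−3.72, SE 0.43) and Cdkn1a (−1.51, SE 0.43) fell. The largest rises were those of Lrrc4b (5.50), Cdk14 (4.35), the antisense gene Gm20655 (4.22), the vesicle protein gene Dmxl2 (4.16, from 38.3 to 683 CPM) and Gm43285 (4.08), a locus of unsettled coding status, alongside the higher Slc34a2 share on day 14. In total 1148 genes rose and 997 fell, 72 of them on X and 8 on Y.

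Camera passed 13 of 32 lists between days 14 and 8. None of these passed with an estimated correlation. Of 14 monocyte genes 9 rose, with Csf1r (2.18), Ly86 (2.55) and Cybb (1.83) among them, and 10 adjusted over the list alone (median 1.51, camera adjusted p = 7.2e-11, and adjusted p = 0.85 with an estimated correlation). Primary granule and granulocyte priming genes had 5 of 11 higher, 5 also adjusted over the list alone (median 0.59, and adjusted p = 0.85 with an estimated correlation), including Fcnb (3.55) and Prtn3 (1.0). Of 15 cytokine receptors 5 rose, including Csf2ra (1.57) and Il6st (1.10, and −1.03 with cells of at least 200000 reads), with 7 higher and 1 lower adjusted over the list alone (median 0.68, and adjusted p = 0.85 with an estimated correlation). Of 25 ribosome biogenesis genes 13 fell, such as Ncl (−1.31) and Rrp1b (−1.40), 15 adjusted over the list alone (median −0.83, camera adjusted p = 3.02e-06, and adjusted p = 0.85 with an estimated correlation). Of 19 fluoropyrimidine genes 5 fell, such as Mthfd2 (−2.35, SE 0.32) and Mthfd1 (−0.89), 7 adjusted over the list alone (median −0.50, and −0.45 with 1 member at 0 reads on day 14 set to its bound, and adjusted p = 0.85 with an estimated correlation). Basophil and mast cell genes had 4 of 8 lower, with 5 lower and 1 higher adjusted over the list alone (median −2.73, and −2.14 with Prss34 at its bound of at least 2.43 lower, from 7.43 and 0.036 CPM in the day 8 sets, of which the second had 1 read). These had adjusted p = 0.85 with an estimated correlation. Erythroid genes had 3 of 5 lower, 3 also adjusted over the list alone (median −3.38, with Klf1 at 0 reads on day 14 and at least 3.92 lower, and adjusted p = 0.85 with an estimated correlation). Of 17 stem and multipotent progenitor genes 4 fell, Ifitm1 (−2.74), Angpt1, Adgrg1 (−2.07) and Procr, 5 adjusted over the list alone (median −0.21, and −0.52 and 0.12 without the first and the second day 8 set, and adjusted p = 0.85 with an estimated correlation). Procr, at 1.34 and 3.21 CPM in the day 8 sets and 0 reads on day 14, was at least 1.56 lower. Without the second day 8 set it was at least 0.84 lower. Glycolysis genes had 4 of 17 lower, such as Slc16a3 (−2.81) and Ldha (−1.10), 5 adjusted over the list alone (median −0.53, and adjusted p = 0.85 with an estimated correlation). Oxidative phosphorylation had 2 of 22 lower, Cyc1 (−0.90) and Atp5b (−0.87), none adjusted over the list alone (median −0.33). Stroma and endothelium had 1 of 6 higher, Emcn (1.39), 4 adjusted over the list alone (median 1.45). This list and oxidative phosphorylation had adjusted p = 0.85 with an estimated correlation. DNA replication genes had 10 of 42 lower, such as Casp8ap2 (−1.71) and Ccne2 (−1.53), 13 adjusted over the list alone (median −0.49, camera adjusted p = 3.36e-05, and adjusted p = 0.859 with an estimated correlation). Immediate early genes had 4 of 16 higher and 1 lower, with Hspa1a at 3.57 and Hsp90aa1 at −1.0, 5 and 2 adjusted over the list alone (median 0.41, camera adjusted p = 0.0294, and adjusted p = 0.899 with an estimated correlation).

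Gfi1 (0.03), Cebpa (−0.43), Cebpe (0.59), Cd34 (−0.61), Ly6a (0.84), Flt3 (−0.73), Mki67 (−0.03), Ctnnb1 (−0.44), Myc (−0.51) and Tyms (−0.16) were not called between days 14 and 8. The edgeR count of 2145 became 875 in limma voom (680 higher and 195 lower), 1060 in DESeq2 (530 and 530) and 2982 with cells of at least 200000 reads (1000 and 1982). On thinned cells it became 0 in edgeR (2629 at an unadjusted p under 0.05), 0 in limma voom (1883) and 199 in DESeq2 (167 and 32), with 2064 of 2065 tested calls in the same direction on thinned sums.

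**Figure D4:**
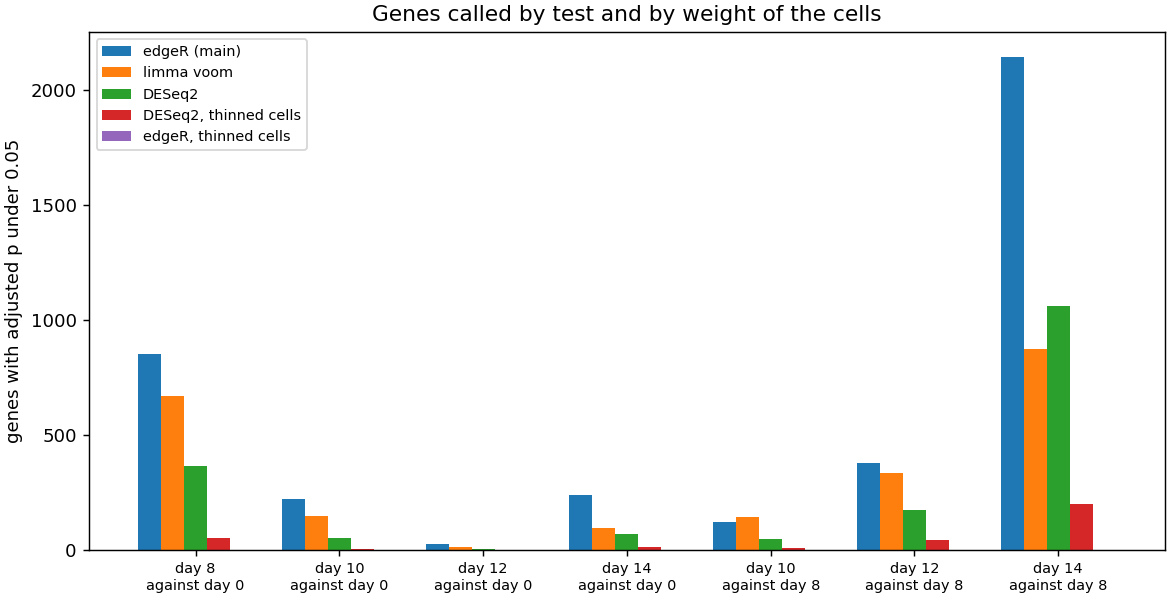
Genes with an adjusted p under 0.05 (vertical axis) in each of the 7 comparisons (horizontal axis) by edgeR, limma voom and DESeq2 on summed counts and by DESeq2 and edgeR on cells thinned to 50000 reads. For day 8 against day 0 the counts were 853, 669, 363, 49 and 0.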

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

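Of the tests described here, those on cells with at least 4000 genes, on sex and on depth were chosen after the result was seen. Predictions for the tests on Slc34a2 and on thinned sums were written before the results of those tests. The fits used for thinned sums, limma voom and DESeq2 on thinned cells, were themselves added after seeing the data.

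The change from day 0 differed between days for several genes, tested as the later day against day 8 in edgeR. Between days 10 and 8 the difference in log2 fold change was 2.14 for Elane, 1.39 for Mpo, 1.70 for Fcgr3 and −1.83 for Cdkn1a. Between days 12 and 8 it was 1.48 for Irf8, 2.51 for Elane, 1.45 for Mpo, 1.31 for Fcgr3 and −1.60 for Flt3. Between days 14 and 8 it was 1.58 for Irf8, 2.82 for Elane, 1.08 for Mpo, 0.83 for Kit, 1.62 for Fcgr3 and −1.51 for Cdkn1a. In the 49 day 14 cells left out as shallow, Slc34a2 took a median of 78.3% of reads, against 18.03% in kept day 0 cells. Among cells left out on other days the median was 32.4% on day 0 (4 cells), 25.7% and 38.9% in the day 8 sets (6 cells and 1 cell), 41.9% on day 10 (3 cells) and 71.4% on day 12 (10 cells). A high share in shallow cells was therefore not particular to day 14. The median ratio of reads in genes to spike-in reads was 78.9 and 71.8 in the day 8 sets, against 40.9 on day 0.

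Genes were higher on day 14 in a set with few reads and a high Slc34a2 share, and within the 92 day 0 cells the 125 of them tested (Slc34a2 and Y-linked genes left out) had a median Spearman correlation of 0.058 with the Slc34a2 share. Random lists matched on expression had a median of −0.12 and an upper limit (the top of their central 95%) of −0.088, which put the genes at percentile 100 of 10000 lists. A candidate explanation is therefore that part of the rise reflects reads that take a larger share where a cell gave little cDNA. The count was 318 without cells under 4000 genes against 239 with them, but the former fit had an infinite prior for the spread, so these counts decide nothing. Cells with few detected genes and a biological change by day 14, which was not tested, stay open.

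The monocyte list was lower on day 8 than on day 0, between a male and a female group of sets. A difference between the sexes as the whole cause is argued against by the male sets alone, mainly by the single shallow day 14 set, where the list's median was 1.51 higher than on day 8. On day 10, also male, it was 0.35 higher than on day 8 (0.89 on thinned cells), the first of these under the 0.5 set for this test. On thinned cells, which all have the same number of reads, the median was −1.54 against −1.61. This argues against the larger weight of deeper day 8 cells in the sums as the cause. Thinning keeps each gene's expected share of a cell's reads, so it cannot decide on other effects tied to depth, which stay open. A response to 5-FU may account for the lower list. Bone preparation and the mice may also differ between days, which the labels do not resolve, and a partial effect of sex stays open.

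On thinned sums edgeR called no gene between days 8 and 0, with 1431 at an unadjusted p under 0.05. An unstable prior for the spread in edgeR was predicted to leave other tools with over 0.5 of their calls, and this prediction was not met. DESeq2 made 13.5% as many calls as on full sums (49 against 363) and limma voom made 0 (669 on full sums, 1392 at an unadjusted p under 0.05 on thinned ones). All 832 of 832 tested calls had the same direction on thinned sums, which was nearly fixed in advance because these are drawn from the same reads. In limma voom the spread also came from 1 residual degree of freedom and a prior, so its 0 calls cannot decide. Only the DESeq2 count bears against an unstable prior, and the edgeR prior fell from 51.5 to 3.22 degrees of freedom on thinned sums. What ended the calls therefore stays open, an unstable prior included, and no biological explanation was tested.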

How the results depend on the processing

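The alternatives with at least 4000 genes per cell, without the day 14 set, without Slc34a2 and CT010467.1, and with limma voom or DESeq2 on thinned cells were chosen after seeing the data. Depth limits the results, with a median of 79451 reads per kept cell on day 14. For named genes, DESeq2 size factors kept direction and side of the threshold in 455 of 475 results and left 19 short of it, limma voom kept 420, the DESeq2 Wald test 393 and cells of at least 200000 reads 386. On thinned cells edgeR kept 224 and left 234 in the same direction short of the threshold. Of the 84 called lists, 81 passed with DESeq2 size factors, 79 without a cell filter, 79 with cells of at least 4000 genes and 59 on thinned cells. Without Slc34a2 and CT010467.1 all 7 counts of called genes stayed within 1.5 times. Leaving out a day 8 set leaves no residual degrees of freedom, so it gives fold changes with no test. Without the first, 82 of 475 named gene values moved by more than their standard error. Of 84 list medians 33 moved, by more than the standard deviation of the 2 medians with a day 8 set left out. Without the second, 70 gene values and 18 list medians moved, and 1 gene and 2 lists turned. The totals include days 10, 12 and 14 against day 0, which hold no day 8 set. A list median that lies between the 2 medians with a set left out can count as moved for at most 1 of them. These counts therefore understate how far results rest on 1 day 8 set. Of the called genes, the share that was higher ran over the alternatives from 256 of 669 to 401 of 708 for day 8 against day 0, from 60 of 149 to 3 of 4 for day 10 and from 7 of 20 to 37 of 63 for day 12. It ran from 564 of 1717 to 11 of 12 for day 14 against day 0. Against day 8 it ran from 22 of 43 to 5 of 7 for day 10, from 21 of 44 to 215 of 336 for day 12 and from 1000 of 2982 to 167 of 199 for day 14. No paired analysis was possible because days other than day 8 have 1 set each. Shares of cells moved beyond their counting interval in 71 of 144 results without thinning.

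For day 8 against day 0, 853 genes were called, and 363 by the DESeq2 Wald test. For day 10 against day 0 the counts were 220 and 52. For day 12 against day 0 edgeR called 26, DESeq2 4, limma voom 11, edgeR with DESeq2 size factors 16, without a gene filter 73, with cells of at least 200000 reads 63, with at least 4000 genes 81 and without the day 14 set 66. For day 14 against day 0 the count was 239, with 67 by DESeq2, 96 by limma voom, 564 without a cell filter and 1717 with cells of at least 200000 reads. For day 10 against day 8 it was 120, with 45 by DESeq2, 75 with DESeq2 size factors, 43 with cells of at least 200000 reads and 186 with at least 4000 genes. For day 12 against day 8 DESeq2 called 171 against 378, and for day 14 against day 8 DESeq2 called 1060 and limma voom 875 against 2145. On thinned cells DESeq2 called 49, 4, 0 (71 at an unadjusted p under 0.05), 12, 7, 44 and 199 in the same order of comparisons. On thinned cells edgeR called 0 in each of the 7, with 1431, 706, 517, 1227, 581, 1134 and 2629 at an unadjusted p under 0.05. On thinned cells limma voom also called 0 in each, with 1392, 575, 356, 709, 574, 1041 and 1883. Fits without a gene filter, with at least 4000 genes or without the day 14 set had an infinite prior for the spread, and thinned cells a prior of 3.22 degrees of freedom against 51.5. Camera lists numbered 18, 11, 7, 5, 14, 16 and 13, became 0 in each comparison with an estimated correlation, and became 1 on thinned cells for day 12 against day 0. With 1 residual degree of freedom the estimated correlation could hardly let any list pass, so these counts of 0 decide nothing. The prediction for an unstable prior on thinned cells was not met in DESeq2, but limma voom could not decide on it. That explanation stays open, and the cause was not tested otherwise.

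Log2 fold changes that turned are given next, and the cause was not tested. Of these genes, Cpa3 (day 10 against 8), Il6st (day 14 against 8) and Prg2 (day 12 against 8) were called. Without a gene filter the sign was opposite for Tyms 0.021 (day 8 against 0), Mpo 0.040 (day 10 against 0), Cd34 −0.012 (day 14 against 0), Gfi1 −0.098 (day 14 against 8). In edgeR on thinned cells the sign was opposite for Tyms 0.015, Epx 1.38, Siglecf −0.53 (day 8 against 0), Mpo −0.038, Kit −0.10, Flt3 0.21, Cdkn1a −0.63 (day 12 against 0), Cebpa 0.0067, Cd34 −0.0057, Siglecf −0.080 (day 14 against 0), Mki67 −0.10, S100a9 −0.29, Cpa3 0.00060, Apoe 0.33 (day 10 against 8), Ly6a 0.037 (day 12 against 8), Mki67 0.083 (day 14 against 8). In limma voom on thinned cells the sign was opposite for Tyms 0.011, Epx 0.30, Siglecf −0.58 (day 8 against 0), Mpo −0.038, Kit −0.10, Flt3 0.21, Cdkn1a −0.63 (day 12 against 0), Cebpa 0.011, Cd34 −0.0050, Siglecf −0.071 (day 14 against 0), Mki67 −0.10, Cpa3 0.12, Apoe 0.40 (day 10 against 8), Ly6a 0.094 (day 12 against 8), Mki67 0.085 (day 14 against 8). In DESeq2 on thinned cells the sign was opposite for Tyms 0.020, Epx 1.40, Siglecf −0.52 (day 8 against 0), Mpo −0.037, Kit −0.10, Flt3 0.21, Cdkn1a −0.63 (day 12 against 0), Cebpa 0.050, Siglecf −0.037 (day 14 against 0), Mki67 −0.10, S100a9 −0.30, Apoe 0.32 (day 10 against 8), Ly6a 0.032 (day 12 against 8), Mki67 0.12 (day 14 against 8). Without a cell filter the sign was opposite for Siglecf −0.028 (day 8 against 0), Cd34 −0.042 (day 14 against 0), Gfi1 −0.061 (day 14 against 8). In limma voom the sign was opposite for Siglecf −0.0026 (day 8 against 0). Without the day 14 set the sign was opposite for Siglecf −0.0046 (day 8 against 0). With cells of at least 200000 reads and 2000 genes the sign was opposite for Cd34 −0.019, Flt3 −0.038, Gata1 −2.62 (day 10 against 0), Siglecf 0.41 (day 12 against 0), Gfi1 −0.020, Cd34 −0.0087 (day 14 against 0), Ly6g −0.34 (day 10 against 8), Cd34 0.040, Mki67 0.062, Prg3 0.78, Epx 0.20, Siglecf 0.21, Slc40a1 −0.58 (day 12 against 8), Gfi1 −0.52, Sparc −5.85, Il6st −1.03 (day 14 against 8). With DESeq2 size factors in edgeR the sign was opposite for Cebpa 0.0013 (day 14 against 0). With cells of at least 4000 genes the sign was opposite for Cebpa 0.052 (day 14 against 0), Mki67 0.029 (day 14 against 8). In the DESeq2 Wald test the sign was opposite for Cebpa 0.0013 (day 14 against 0). Without the second day 8 set Prg2 had 0 reads on both day 12 and day 8, so Prg2, day 12 against day 8, had a fitted log2 fold change of 0.0 there and −14.51 without the first (fitted against 0 reads, so no bound), and the sign was opposite for the median of the list eosinophil, day 12 against day 8, 0.36 (−1.95 without the first) and the median of the stem and multipotent progenitor list 0.12 (day 14 against 8).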

Other observations

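Neither of the following descriptions rests on a test, and both were chosen after the values were seen.

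Per cell, primary granule and granulocyte priming genes took a median of 7.56% of reads on day 0, 3.43% and 2.56% in the day 8 sets, 7.52% on day 10, 7.34% on day 12 and 5.97% on day 14. Monocyte genes took 0.564% on day 0, 0.0292% and 0.0245% on day 8, 0.104% on day 10, 0.397% on day 12 and 0.269% on day 14. By the mean over cells the fall was smaller, with 0.633% on day 0, 0.141% and 0.071% on day 8 and 0.234% on day 10. Stem and multipotent progenitor genes took 0.0319% on day 0, 0.111% and 0.161% on day 8 and 0.0783% on day 10. With cells of at least 200000 reads, of which day 14 had 4, primary granule and granulocyte priming genes took 8.33% on day 0 and 10.3% on day 14, and monocyte genes 0.578% on day 0, 0.609% on day 12 and 0.820% on day 14, so the order of these days depends on the cells kept. The kept cells fell into 9 clusters (5 at resolution 0.5, 16 at resolution 2 and 12 with 10 principal components) over which the sets were spread unevenly, and because their leading genes differ between days, cluster sizes are not compared.

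H2-Q6, a nonclassical class I gene, stood at 46.7 CPM on day 0, 3.73 and 6.57 in the day 8 sets, 3.31 on day 10, 47.5 on day 12 and 25.5 on day 14. The processed pseudogene Gm7676 stood at 3.67, 26.5 and 44.99, 34.9, 2.21 and 5.74 CPM on the same days. Both genes had values on days 0 and 12, the female sets, that lay far from those on days 8 and 10, with day 14, a male set, in between. For Gm7676, day 14 lay nearer the female sets, so the values do not split by sex alone.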
